A study of Homo sapiens with 2 samples.

How the data were processed

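The series measured N6-methyladenosine (m6A) in the messenger RNA of HEK293T cells, an established line derived from human embryonic kidney, with GLORI. In this assay glyoxal and nitrite convert unmethylated adenosine to inosine, which is sequenced as G, whereas m6A resists the reaction and is still read as A. Per the labels, oligo(dT)-purified mRNA of wild-type cells, 100 to 200 ng for each library, was treated and made into libraries by a modified eCLIP procedure. The labels give 2 replicates of 1 group and no second group, so the comparisons possible are between the replicates, between sites and between genes. Nothing in the labels says that the replicates came from separate cultures, so differences between them measure only the spread between these libraries, which can be technical.

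The authors deposited 1 list of called sites for each replicate. Per the file headers, each line gives the chromosome, position, strand and gene name of a site, the count of reads showing A or G, the count of reads showing A, and their ratio. In both files the ratio equalled the A count over the A plus G count within 5e-06, so this deposited fraction is the methylation level. Per the file headers the lists also give a conversion fraction and a coverage for each gene, and a p-value with its adjusted value for each site. How the authors computed the deposited gene coverage is not given in the sources used here, and it was used here only to group genes of like depth. The deposited p-value was recomputed as the upper binomial tail of the A count at 1 minus the conversion fraction. Of the values above 0, 99.3% in replicate 1 and 99.4% in replicate 2 came out within 0.1 on the log10 scale. The submitters' processing notes name Trim Galore 0.6.6, STAR, Bowtie, SAMtools and the genome build GRCh38, without roles or settings; the site caller and the gene annotation are not given in the sources used here.

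The files hold only sites that passed the authors' limits. The smallest coverage in either file was 15 reads, the smallest A count 5, and the smallest level 10%. The largest adjusted p-value was 0.00401 in both. Sites that failed these limits are not listed, so a site or gene without an entry may lack methylation or depth. At 15 reads, 5 A reads allow no level below 33.3%, so weakly covered genes can show only their more methylated sites. Replicate 1 listed 72449 sites with 5221660 reads of A or G in total, and replicate 2 listed 81554 sites with 6306522. These totals cover listed sites and are not the depth of the libraries. Median coverage per site was 40 reads in replicate 1 and 42 in replicate 2.

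A shared site has the same chromosome, position and strand in both files, and its level is the mean of both levels. The lists of the 2 replicates were compared by their overlap with 95% Wilson intervals, and shared sites by Pearson's and Spearman's correlation across sites. Fisher's exact test, two-sided, was run on the A and G counts of each shared site with Benjamini-Hochberg adjustment at 0.05. The levels of shared sites differed between the files by no more than the sampling of reads, so the files were counted as 1 sample. Values are given for each file or as their mean, with no SD. Errors of genes are counting standard errors of the mean level over shared sites, and intervals of single sites are 95% Wilson intervals on the summed counts. Both cover counting error only. Reads are not shown to be independent molecules, since the use of molecular identifiers is not given in the sources used here.

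A gene's level is the mean over its shared sites. There were 31 gene lists, of which 29 had at least 5 genes with a shared site and were tested. Each list's median level and median number of shared sites was set against 10000 random lists of the same size drawn, with replacement, from genes in the same deciles of gene coverage. The two-sided p-value is the rank among those lists, at the smallest 0.0002, and was adjusted over the 29 lists for each measure. Genes are not replicates, so these values describe these libraries. Lists were defined by symbols or symbol patterns. The patterns also caught genes of another kind. By the biotypes below, 48 members in 7 of the 29 lists were pseudogenes, among them 14 of 45 SR and hnRNP genes, 4 of 173 ZNF genes and 2 of 47 oxidative phosphorylation genes. Other members of another kind include RPL7L1 in the ribosomal protein list and the readthrough gene ATP5MF-PTCD1 in the oxidative phosphorylation list. Biotypes and gene ends came from NCBI RefSeq's annotation of GRCh38.p14, in which 9384 of 9521 gene names were found (98.6%).

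The groups, the gene lists, the rule for named genes and the planned tests and alternatives were fixed before the data were examined; the alternatives for strand, spacing, the last 10% of the gene and pseudogenes were added afterwards. The rule takes the 12 genes with the most shared sites, the 8 with the highest and the 8 with the lowest mean level among genes with at least 5 shared sites, all members of the list of m6A writers, erasers and readers, and the 3 members with the most shared sites in each other list. It adds MALAT1, MYC, ACTB, GAPDH, MAT2A and NORAD whatever their values, the 5 sites with the highest smaller coverage of the 2 replicates, and the highest site with at least 50 reads in both replicates in each of these 6 genes. It would also take sites that differed between replicates after adjustment, of which there were none. Not all genes it takes are printed.

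Neither a genome sequence nor a transcript annotation was used here. The planned results on the DRACH motif, on transcript regions, on stop codons, on exon junctions and on the clustering of sites were therefore not run. Similarity of neighbouring sites was planned for DRACH sites along spliced transcripts. It was run on all shared sites of named genes at most 30 nt apart on the genome, against 1000 shufflings of levels within genes. Numbers of sites per gene were not divided by transcript length. The analyses of strand, spacing, position along the gene, gene starts, biotypes and mitochondrial sites were chosen after the files were seen.

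The tests were tested on simulated data. With reads drawn at the measured levels and depths of all 60462 shared sites, and 200 sites of at least 100 reads shifted, Fisher's test found 51 of 100 shifts of 20 points and 100 of 100 shifts of 40 points. It made 4 calls among the 60262 unshifted sites. The list test, run with fewer random lists than the 10000 used on the data, found 10 of 10 lists of 30 genes shifted by 20 points. It called 0 of 20 unshifted lists. Smaller shifts of lists, and shifts at sites with fewer than 100 reads, were not simulated. Alternatives were coverage of at least 30 or 50 reads, a level of at least 20%, the authors' adjusted p under 0.0001, each replicate alone, thinning to 15 reads, a tolerance of 1 nt in position, other tests and weights, and other matching of gene lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.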

Results

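Methylated adenosines of HEK293T messenger RNA were listed at single-base resolution in 2 GLORI libraries of untreated wild-type cells. The series states as its purpose a description of the GLORI workflow and an evaluation of its performance. Replicate 1 listed 72449 sites, of which 66665 lay in 10321 named genes. Replicate 2 listed 81554 sites, of which 74351 lay in 10879 named genes. Coverage per site ran from 15 to 11943 reads in replicate 1 and to 13934 in replicate 2.

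The first comparison asked how closely the replicates matched in the sites they listed and in the level of each site. The most deeply covered sites lay in translation genes and had nearly equal levels in both libraries. In RPL41, which encodes a ribosomal protein, position 56117608 of chromosome 12 (plus strand, GRCh38) was methylated at 61.4% in replicate 1 (11943 reads) and 60.8% in replicate 2 (13934 reads). Position 56117748 of the same gene had levels of 68.3% and 68.0%. In EEF2, the elongation factor that moves the ribosome along the mRNA, position 3976520 of chromosome 19 (minus strand) had 38.8% and 38.9%, and position 3976564 had 28.1% and 28.3%. RPSA, another ribosomal protein gene, had 11.7% and 11.3% at position 39411962 of chromosome 3. Fisher's exact test separated the replicates at none of these 5 sites (adjusted p = 1 at each).

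Both replicates listed 60462 sites out of 93541 in either. These were 83.5% of the sites of replicate 1 (95% Wilson interval 83.2 to 83.7) and 74.1% of those of replicate 2 (73.8 to 74.4), and 64.6% of the union. Detection rose with coverage: replicate 2 listed 76.1% of the replicate 1 sites with 15 to 29 reads and 93.6% of those with at least 200. In the other direction, replicate 1 listed 53.5% and 93.4% of the replicate 2 sites in these ranges. Detection also went with the level, from 62.9% of replicate 1 sites methylated at 10 to 20% to 93.7% of those above 80%, and from 57.4% to 84.7% of replicate 2 sites. Sites found only in replicate 1 numbered 11987 and had a median level of 21.4% and a median coverage of 30 reads. The 21092 sites found only in replicate 2 had a median level of 26.9% and 25 reads, against 44.6% and 45.5 reads for shared sites.

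Across shared sites the levels of the replicates correlated with a Pearson r of 0.942 and a Spearman rho of 0.937; sites are not independent replicates. The median absolute difference was 4.95 percentage points, and 95% of sites differed by less than 19.6 points. Fisher's exact test found 0 sites with an adjusted p under 0.05, and 1850 sites (3.06%) had an unadjusted p under 0.05, against 2.90% in reads simulated at equal levels. A chi-square test scaled by the estimated dispersion also called 0 sites after adjustment and had 3027 under an unadjusted 0.05. The mean chi-square of the level difference was 0.936 (95% interval over genes 0.925 to 0.946), against 0.945 in the simulation. At the 1713 sites with at least 300 reads in both, it was 0.939 (0.875 to 1.004) and r was 0.996. At shared sites the levels of the libraries differed by no more than the sampling noise, and the libraries were counted as 1 sample. Sites listed in 1 library only were not part of these tests. Coverage differed slightly more than sampling at well covered sites. The most covered shared site of each gene was taken, and in 5481 genes it had at least 120 reads in total. Over these sites the mean chi-square of the split of reads was 1.09 (chi-square test, p = 5.0e-06).

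**Figure D1:**
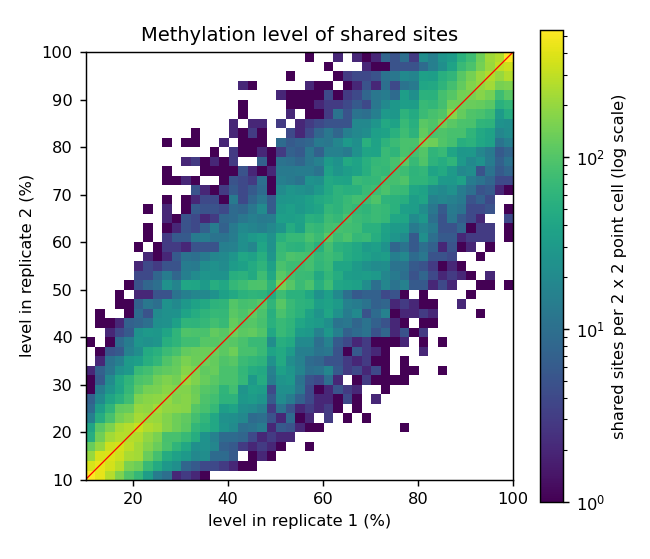
Methylation level in replicate 1 (x axis, %) against replicate 2 (y axis, %) for the 60462 shared sites, with colour giving the number of sites in each cell on a log scale and the line marking equality. Sites lie along the line of equality, with r of 0.942 and a median absolute difference of 4.95 points.

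Levels covered the whole listed range. The median over shared sites was 44.6%, with quartiles at 25.8% and 73.5%, and the medians were 45% in replicate 1 and 44.6% in replicate 2. At 27110 sites (44.8%) the level was at least 50%, and at 11955 (19.8%) at least 80%; 15.2% of sites lay under 20%. Because the lists start at 10%, these medians describe listed sites and not all adenosines.

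Shared sites fell in 9521 named genes, with a median of 4 sites per gene and quartiles of 2 and 8. Genes with many sites included SPEN, a transcriptional repressor, with 91 sites at a mean level of 47.2% ± 0.32 (counting SE, 1 sample), and single sites from 10.51% to 97.8%. SON, a nuclear speckle protein, had 83 sites at 46.8% ± 0.34, and SRRM2, another speckle protein, had 58 sites at 32.0% ± 0.26. The histone methyltransferase genes KMT2D and KMT2A had 81 and 63 sites at 56.2% ± 0.49 and 44.0% ± 0.57. XIST, a long noncoding RNA, had 64 sites at 40.4% ± 0.21. MKI67, the proliferation marker, and RNF213 had 62 sites each, ASXL1 had 59, SRCAP 56, ARHGAP35 54 and SLITRK5 52. At the other end 2234 genes (23.5%) had 1 shared site, while the 424 genes with at least 20 held 20.7% of the sites. Between replicates, the number of sites per gene correlated with a rho of 0.931 and the mean level with 0.834, across genes.

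Among genes with at least 5 shared sites, the mean level ran from 14.5% to 92.5%. The highest belonged to MAFG-DT (92.5% ± 1.6, 6 sites), a divergent transcript, OCLN, which encodes the tight junction protein occludin (89.4% ± 1.7, 5 sites), and SPATA2 (89.4% ± 1.7, 5 sites). CENPL followed at 87.7%, ABCC10 at 86.8%, IGSF3 at 84.7%, DACT1 at 84.4% and MAT2A, which encodes S-adenosylmethionine synthetase, at 84.3%. The lowest belonged to METTL26 (14.5% ± 0.84, 6 sites) and DDT (14.5% ± 0.54, 5 sites). GNAS, which encodes a stimulatory G protein alpha subunit, had 15.4% ± 0.75 over 6 sites, HMG20B 15.8%, SMARCC2 16.3%, CDIPT 16.9%, KIAA1191 17.1% and PTPRU 17.6%. Median site coverage in replicate 1 was 16 to 33 reads in 7 of the 8 highest genes, and up to 578.5 in the lowest (GNAS). All 8 lowest genes were covered more deeply than these 7. Only MAT2A among the highest, with 153 reads, overlapped them in depth, lying above KIAA1191, SMARCC2 and CDIPT (134). Because a listed site had at least 5 A reads, weakly covered genes can show only their more methylated sites. The ranking therefore does not separate level from depth. Over all genes the mean level fell with gene coverage (rho = -0.418 across genes), from a median of 58.6% in the lowest coverage decile to 31.02% in the highest.

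Of the 6 genes named in advance, 5 had shared sites. MYC, the proto-oncogene transcription factor, had 19 at a mean of 50.5% ± 0.54, and its position 127741016 on chromosome 8 (plus strand) was methylated at 96.7% (54 of 56 and 66 of 68 reads, interval 92.0 to 98.7). ACTB, which encodes beta-actin, had 5 sites at 54.9% ± 1.2, with 85.9% at position 5530601 of chromosome 7 (minus strand, interval 80.6 to 90.3). This position is the annotated first nucleotide of ACTB, and it enters the mean of the gene. The same holds for a shared site in each of NORAD, PTPRU, AMOT and PPP1R15B. The 5 sites of MAT2A lay between 76.2% and 91.9%, the highest at position 85543815 of chromosome 2 (plus strand, 162 and 160 reads, interval 88.4 to 94.4). The long noncoding RNAs NORAD and MALAT1 had 9 and 7 sites with means of 64.9% ± 1.6 and 47.6% ± 1.7. Among their sites with at least 50 reads in both replicates, position 36050514 of chromosome 20 (minus strand) in NORAD had 92.2% (86.6 to 95.8) and position 65500372 of chromosome 11 (plus strand) in MALAT1 had 70.8% (64.1 to 76.3). GAPDH, a glycolytic enzyme gene, had 0 listed sites in either replicate; unlisted sites give no bound on its level.

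The m6A machinery was itself methylated: 21 genes of the list had shared sites. RBM15 and RBM15B, adaptor subunits of the methyltransferase complex, had 41 and 33 sites at 55.8% ± 0.52 and 54.2% ± 0.66. WTAP had 21 sites at 46.2% ± 1.1 and VIRMA 15 at 56.4% ± 1.4. METTL3 and its partner METTL14 had 3 sites at 36.2% ± 2.1 and 4 at 52.8% ± 3.4. The median number of shared sites in their coverage deciles was 4 and 2. METTL16, a separate methyltransferase, had 6 sites at 81.6% ± 1.8. The cytosolic readers YTHDF1, YTHDF2 and YTHDF3 had 16, 24 and 12 sites at 63.3% ± 1.1, 64.5% ± 0.63 and 70.9% ± 1.6. The demethylase genes ALKBH5 and FTO had 19 sites at 30.9% ± 0.56 and 6 at 26.2% ± 1.8, and the reader IGF2BP1 had 9 at 29.02% ± 0.94. As a list (n = 21 genes) they were not called against random genes of like coverage: the median level was 52.1% against 45.05% (adjusted p = 0.386), and the median number of sites 7 against 4 (adjusted p = 0.369). In replicate 2 alone (n = 22 genes) they had 11 sites against 5 (adjusted p = 0.0141).

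Gene lists were compared next, by number of shared sites and by level, each against random genes of like coverage. The matching was by decile, and the highest decile of gene coverage ran from 131.3 to 7763.7. Depth was therefore matched only loosely for the most covered genes, and differences in depth within a decile were not tested. More sites than in random lists were found in 5 of the 29 lists. The 23 immediate early genes, which are induced within minutes of a stimulus, had a median of 11 sites against 3 in random lists, with 18 above and 4 below the median of their coverage decile; JUN had 33, MYC and IER5 19 each. The 46 histone methyltransferases and demethylases had 11 against 4 (36 above, 8 below), led by KMT2D, KMT2A and NSD1 with 51. The 68 homeobox, SOX and FOX transcription factors had 8.5 against 3 (51 above, 11 below), with 47 in FOXO3, 39 in FOXK2 and 38 in SOX4. The 173 ZNF zinc finger genes had 6 against 3 (109 above, 43 below), with 32 in ZNF318 and 31 each in ZNF629 and ZNF618. These 4 lists had an adjusted p of 0.00145. The Wnt pathway genes (n = 32 genes) had 8 against 3 (22 above, 7 below, adjusted p = 0.00483), with 26 in BCL9, 24 in FZD7 and 19 in ZNRF3, but the call was lost at a coverage of at least 30 reads (adjusted p = 0.143) and of at least 50 (0.334).

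A pair of lists had fewer sites. The nuclear oxidative phosphorylation genes (n = 47 genes) had a median of 1 site against 3 (9 above, 32 below, adjusted p = 0.00464), and the cytosolic ribosomal protein genes (n = 34 genes) 1 against 2.5 (8 above, 19 below, adjusted p = 0.0315). ATP5IF1, an inhibitor of ATP synthase, had 7 sites at 20.8% ± 1.6, RPL28 had 12 at 34.5% ± 1.3 and RPL13 had 10 at 37.0% ± 1.1. The ribosomal call was kept in 1 of 7 alternatives, and the oxidative phosphorylation call in 5 of 7. In all, 7 of 29 lists were called for the number of sites. Sites were not counted per length of transcript, which differs between these groups of genes.

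For levels, 3 of 29 lists were called. The homeobox, SOX and FOX genes (n = 68 genes) had a median level of 55.5% against 47.0% in random lists (53 above and 15 below their decile's median, adjusted p = 0.0145), and the ZNF genes (n = 173 genes) 56.7% against 51.8% (114 above, 59 below, adjusted p = 0.0232). The oxidative phosphorylation genes (n = 47 genes) had 22.5% against 34.9% (15 above, 32 below, adjusted p = 0.0116). The ribosomal protein genes (n = 34 genes) had 22.8% against 32.9% and missed the threshold (adjusted p = 0.0522). Without replicate 2 they were called lower (n = 39 genes, 20.4% against 28.6%, adjusted p = 0.0333). So were the SR and hnRNP splicing genes (n = 56 genes, 25.9% against 36.1%, adjusted p = 0.00773), which were not called with both replicates (n = 45 genes, 35.4% against 39.6%, adjusted p = 0.472), nor with both and pseudogenes left out (n = 31 genes, 37.63% against 37.60%, adjusted p = 0.994). The 3 calls depended on the setting. At a coverage of at least 50 reads 0 lists were called, though with fewer genes the differences kept their direction: 47.8% against 38.5% in the homeobox list (n = 44 genes, adjusted p = 0.146), 45.5% against 39.3% in the ZNF list (n = 80 genes, adjusted p = 0.272) and 22.3% against 32.2% in the oxidative phosphorylation list (n = 38 genes, adjusted p = 0.146). With random genes also matched on the number of sites the differences were smaller and 0 lists were called: 55.5% against 49.9% (n = 68 genes, adjusted p = 0.116), 56.7% against 53.9% (n = 173 genes, adjusted p = 0.254) and 22.5% against 28.5% (n = 47 genes, adjusted p = 0.465). The matching on the number of sites used only broad classes, the highest of them open-ended, so it was loose for genes with many sites. With a level of at least 20% all 3 calls were lost, at 61.8% against 55.5% (n = 68 genes, adjusted p = 0.0551), 61.3% against 57.9% (n = 171 genes, adjusted p = 0.0812) and 42.3% against 49.8% (n = 32 genes, adjusted p = 0.232). The oxidative phosphorylation call narrowly missed the threshold at a coverage of at least 30 reads (n = 43 genes, 22.5% against 32.5%, adjusted p = 0.0536) and without replicate 2 (n = 52 genes, 23.5% against 30.99%, adjusted p = 0.0570), as did the ZNF call with pseudogenes left out (n = 169 genes, 56.5% against 51.9%, adjusted p = 0.0541).

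**Figure D2:**
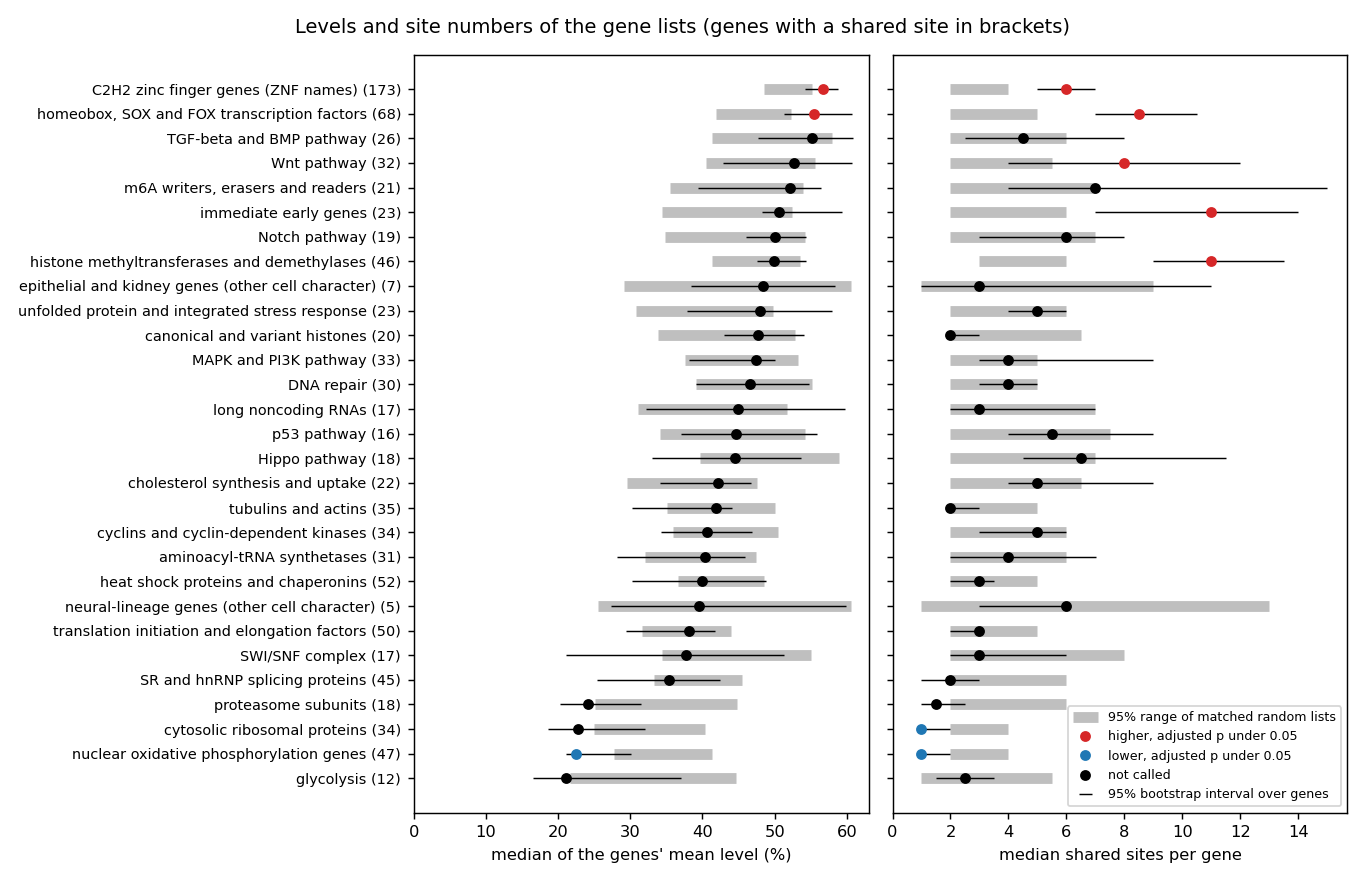
Median over the genes of each list of the mean level (left, %) and of the number of shared sites (right), with 95% bootstrap intervals over genes as lines and the 95% range of random lists matched on gene coverage as grey bars; colour marks an adjusted p under 0.05. The homeobox, SOX and FOX genes lie above the range in both panels (55.5% and 8.5 sites), and the nuclear oxidative phosphorylation genes below it in both (22.5% and 1 site).

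Among classes of transcript, 8430 protein-coding genes held 52985 shared sites and 260 long noncoding RNA genes held 1141. The noncoding genes (n = 260 genes) had a median level of 50.3% against 50.7% in random genes of like coverage (adjusted p = 0.813) and a median of 2 sites against 3 (adjusted p = 0.0244); NEAT1, one of them, had 15 sites at 43.5% ± 0.91. The pseudogenes (n = 681 genes) had 40.3% against 43.9% and 1 site against 3 (adjusted p = 4.0e-04 for both); reads of a pseudogene and its parent gene can be hard to tell apart.

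Along protein-coding genes, 44.0% of the sites lay in the last 10% of the annotated gene and 21.6% within 1 kb of its 3' end. At the other end, sites gathered at the annotated first nucleotide. Within 5 nt downstream of the start there were 436 sites in 420 genes, 322 of them at the first nucleotide itself, against 764 sites at 50 to 200 nt, a density 14.3 times as high (95% interval 12.7 to 16.0). Their median level was 26.7%, against 34.6% further downstream. Positions in spliced transcripts were not analysed here.

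**Figure D3:**
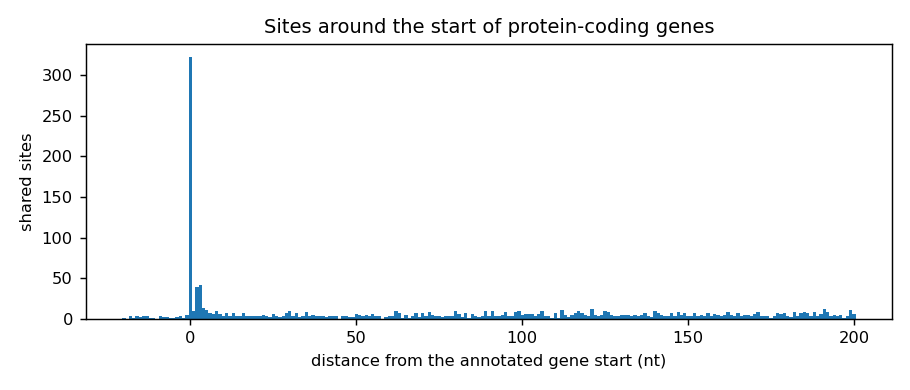
Number of shared sites (y axis) at each distance from the annotated start of protein-coding genes (x axis, nt, 0 is the first nucleotide). The peak at 0 holds 322 sites.

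Neighbouring sites had similar levels to a small extent. Over 10496 pairs at most 30 nt apart in the same gene, the levels correlated with a rho of 0.137, against a mean of 0.0947 (95% range 0.0762 to 0.113) when levels were shuffled within genes (p = 0.002, the smallest that 1000 shufflings can give). Distances between adjacent sites were unevenly spread. Of 11014 distances of 4 to 30 nt, 39.3% were multiples of 3 (95% interval 38.3 to 40.2), against 33.3% for an even spread. In protein-coding genes the share was 39.6%, and in noncoding genes other than pseudogenes and outside named genes 35.2% (31.8 to 38.7). The intervals of these shares treat distances as independent. Distances of 1 to 3 nt were rare, with 56 pairs against 1547 at 4 to 6 nt.

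**Figure D4:**
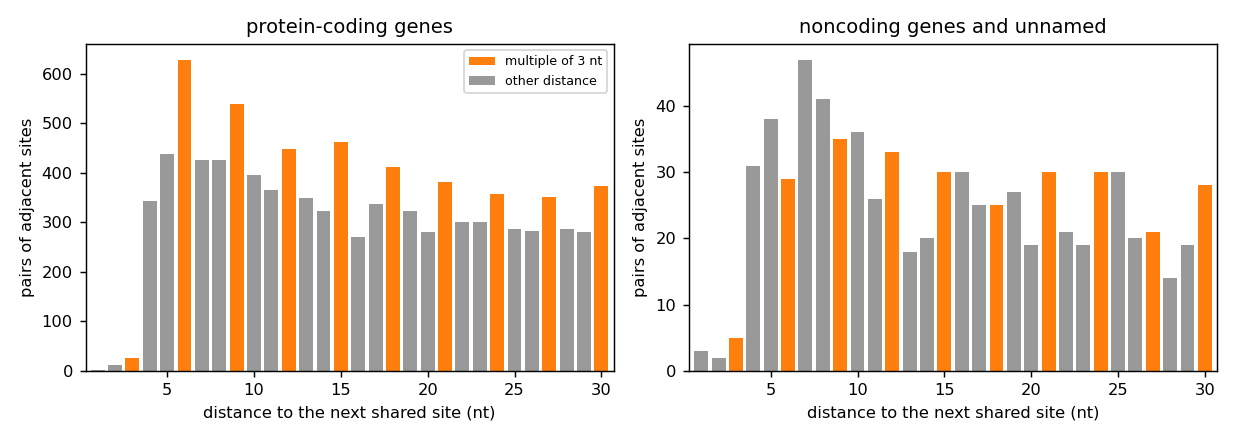
Number of pairs of adjacent shared sites (y axis) at each distance (x axis, nt) in protein-coding genes (left) and in noncoding genes and outside named genes (right), with multiples of 3 nt in orange. Multiples of 3 make up 39.6% of distances of 4 to 30 nt on the left and 35.2% on the right.

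Conversion of adenosine, as the authors list it per gene, had a median of 97.6% in both replicates. The 5th and 95th percentiles were 95.1% and 98.4% in replicate 1, and 95.1% and 98.5% in replicate 2. It correlated between replicates with a rho of 0.929 across genes. Genes with lower listed conversion had higher levels, with a rho of -0.607 in replicate 1 and -0.615 in replicate 2, and more shared sites (rho = -0.494). SPEN had 96.5% and 96.4%, SON 95.6% and 95.7%, and MKI67 95.6% and 96.0%. Whether methylated sites were left out of this conversion is not given in the sources used here.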

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

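Both results of this part were looked at only after the files had been seen, and no control library was there to compare them with. Sites outside named genes and on the mitochondrial chromosome stood out as signal in data that the comparisons of genes did not use. Outside named genes there were 4356 shared sites with a median level of 41.9% and a median coverage of 32.5 reads, against 44.9% and 47 reads in named genes, and 1779 of them had a level of at least 50%.

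The mitochondrial chromosome held 6 shared sites, all on the plus strand and in 5 genes. The small ribosomal RNA gene RNR1 had an adjacent pair, position 1583 at 37.0% (95% Wilson interval 32.9 to 41.4, 235 and 262 reads) and position 1584 at 42.9% (38.6 to 47.3). The large ribosomal RNA gene RNR2 had position 2617 at 40.5% (39.4 to 41.7, 3020 and 3506 reads). ND5, which encodes a subunit of respiratory complex I, had position 13710 at 17.6% (16.3 to 19.2, 1106 and 1409 reads). The transfer RNA genes TRNS2 and TRNV had position 12229 at 39.1% (36.3 to 41.9) and position 1610 at 20.8% (15.4 to 26.8), and replicate 2 alone listed position 614 of TRNF at 14.4% (312 reads). As background, the small mitochondrial ribosomal RNA carries an adjacent pair of dimethylated adenosines near its 3' end, and N1-methyladenosine occurs in the large one, in transfer RNAs and in the ND5 mRNA. The assay reads any adenosine that resists conversion as A, and these data do not tell one modification from another.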

How the results depend on the processing

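Of 70 alternative values, 37 kept to the result reported and 33 did not. A reversal of direction could be scored only for the test of neighbouring sites, and none occurred there. Keeping to the result meant within 1.5 times for a count and within the interval for other values. For the test of neighbouring sites it meant the same side of the threshold. For gene lists the score compares how many were called and not which. With a level of at least 20%, 8 lists were called for number of sites against 7 as reported, but the oxidative phosphorylation (n = 32 genes, adjusted p = 0.0844) and ribosomal (n = 21 genes, adjusted p = 0.614) calls were lost, and the SR and hnRNP (n = 36 genes, adjusted p = 0.0193), translation factor (n = 44 genes, adjusted p = 0.0428) and tubulin and actin (n = 31 genes, adjusted p = 0.0307) lists were called lower. In the lists as reported, pseudogenes made up 14 of 45 SR and hnRNP, 12 of 50 translation factor and 9 of 35 tubulin and actin members. Pseudogenes had a median of 1 site against 3 in random genes. The setting with a level of at least 20% was not run with pseudogenes left out, so these calls may not concern the genes the lists are named after. Without replicate 2, 4 lists were called for level against 3, with the oxidative phosphorylation call lost and the ribosomal and SR and hnRNP calls gained. The rho of neighbouring sites was 0.137 as reported, 0.0894 at 50 reads and 0.060 with a level of at least 20%, still past the threshold. The alternatives for strand, spacing, the last 10% of the gene and pseudogenes were chosen after seeing the data; the cause of the changes was not tested. With coverage of at least 30 reads, the shared part of the union was 64.2%, r 0.965, the median level 37.7%, the median number of sites per gene 3, the share of multiples of 3 nt 40.2%, the plus strand share 58.9% and the last 10% of the gene 44.6% of sites. At 50 reads these were 65.1%, 0.977, 34.2%, 2, 40.7%, 59.3% and 45.1%, and 0 lists were called for level and 4 for number of sites. With a level of at least 20%, the shared part was 65.4%, r 0.920, the median level 55.2%, sites per gene 3 and the last 10% of the gene 43.5%, and 1 list was called for level, the proteasome subunits, which is none of the 3 reported. With the authors' adjusted p under 0.0001, the shared part was 66.6%, r 0.940, the median level 50.04% and sites per gene 3. With each replicate alone the median level ran from 38.9% to 40% and the last 10% of the gene held 43.53% to 43.56% of sites. Thinned to 15 reads, the median level was 46.7% with 0 sites differing (768 at an unadjusted p under 0.05), and weighted by coverage it was 35.1%. Matching random genes also on broad classes of the number of sites left 0 lists called for level. Median conversion was 97.9% in genes of above-median coverage. The coverage, level and p limits all select sites by depth or level, so the median level describes the limit as much as the cells, and depth limits which weak sites can be listed. Not run, for want of a sequence and transcript annotation here, were the planned results on DRACH, regions, stop codons, exon junctions, clustering and 3' UTR levels with their alternatives, and matching lists on DRACH counts. No paired analysis was possible because there is 1 group.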

Other observations

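The lists that follow were not called against random genes of like coverage after adjustment over the 29 lists. In the Notch list (n = 19 genes) MAML1, a coactivator of Notch, had 38 sites at 50.4% ± 0.57 (counting SE) and NOTCH2 27 at 48.8% ± 0.61, with a list median of 49.98% against 44.5% (adjusted p = 0.574). In the TGF-beta and BMP list (n = 26 genes) SKI had 28 sites at 59.9% ± 0.63 and SMAD6 19 at 67.6% ± 1.3, with a list median of 55.2% against 49.99% (adjusted p = 0.506). In the Hippo list (n = 18 genes) AMOT had 28 sites at 34.0% ± 0.50 and FAT1, an atypical cadherin, 26 at 66.6% ± 1.1, with a median of 44.5% against 49.8% (adjusted p = 0.574). IGF1R and IRS4, which act in insulin and growth factor signalling, had 46 sites at 50.04% ± 0.81 and 43 at 46.4% ± 0.24. The 3 protocadherin genes with shared sites were too few to test; PCDH10 had 42 sites at 54.8% ± 0.62 and PCDH7 24 at 66.0% ± 1.2.

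The glycolysis genes (n = 12 genes) had a median level of 21.1% against 33.1% (adjusted p = 0.188), with 6 sites at 19.9% ± 0.72 in PKM and 14 at 44.8% ± 0.94 in HK2. The proteasome subunits (n = 18 genes) had 24.2% against 35.5% (adjusted p = 0.188), although PSMD7 had 4 sites at 65.7% ± 1.6. Counting only sites with a level of at least 20%, the proteasome list (n = 14 genes) was called lower, with 30.6% against 50.2% (adjusted p = 0.0116). Its number of sites was called lower without replicate 2 and with pseudogenes left out. Among synthetases that charge transfer RNAs, the mitochondrial MARS2 had 24 sites at 74.7% ± 0.90, while the list's median (n = 31 genes) was 40.3% against 40.2% (adjusted p = 0.974). The stress response list (n = 23 genes) had 48.0% against 40.7% (adjusted p = 0.386), with 32 sites in PPP1R15B at 48.1% ± 0.67. Of lists for other cell characters, 5 neural genes had a median level of 39.5% (95% range of random lists 25.6 to 60.6) and 7 epithelial and kidney genes 48.4% (29.1 to 60.6).

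The tests of agreement between replicates, and of strand through unnamed sites, coverage and pseudogenes, were chosen after the result was seen; the bounds for spacing, gene starts and sites listed once were written before. The pseudogene test and its bound replaced an earlier one on the plus share of protein-coding genes (53.3%), which the explanation itself would raise; that share and the one of named genes had been seen by then. The design has 1 group, which leaves no difference between groups to set against the technical explanations.

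At shared sites the replicates differed in level by no more than the sampling of reads. Low depth as the reason is argued against by the 1713 sites with at least 300 reads in both, where the mean chi-square stayed at 0.939 (0.875 to 1.004). A candidate explanation is that both libraries draw on 1 library or 1 RNA sample: coverage at sites with at least 1000 reads in total varied between files by 1.11% beyond sampling (95% interval over genes 0 to 1.65). Below 1000 reads it was 2.08% (1.5 to 2.51) from 300 reads, 2.56% (1.93 to 3.09) from 120 and 3.42% (2.57 to 4.17) from 60. At the 16683 sites below 60 it came out at 0, and their mean chi-square of 0.762 lay under the simulated 0.823. Sites there need at least 15 reads in both files, which narrows the split of reads. The estimate of 0 does not allow for this, so it does not show that shallow sites lack a difference. The bands from 60 to below 1000 reads held a small difference beyond sampling. Separate cultures with very even handling stay open, because the labels do not describe the origin of the replicates.

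Adjacent sites lay at multiples of 3 nt more often than an even spread gives, which may reflect the reading frame of coding sequence. In protein-coding genes more than 5 kb from the annotated 3' end the share was 41.8%. It exceeded that of noncoding genes and unnamed sites by 6.67 points (95% interval 2.87 to 10.46). It exceeded that of sites of protein-coding genes within 1 kb of the 3' end by 4.15 points (1.5 to 6.8). Coding sequence and untranslated regions were not told apart in either set. All protein-coding sites exceeded noncoding or unnamed ones by 4.47 points (0.906 to 8.04). This argues, weakly, against a property of any RNA or of the site caller as the whole reason. The intervals of this paragraph treat distances as independent, although many lie in the same gene, and may be too narrow. Of the 5497 noncoding or unnamed sites 4356 were unnamed, and pseudogenes were left out of them. Sites of protein-coding genes within 1 kb of the 3' end still had 37.7% (35.6 to 39.8) and pseudogenes 40.2% (33.8 to 46.9). The reading frame is therefore not shown to be the whole reason. Whether methylation itself or only the placement of motifs has this period was not tested, because no sequence was used here.

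Sites on the plus strand made up 58.2% of shared sites (95% interval over genes 56.8 to 59.6), and more than those on the minus strand on 22 of 23 chromosomes. Sites outside named genes are not the whole reason, since named genes had 57.6%. Reads of minus-strand genes placed on pseudogene copies, 71.7% of which were on the plus strand, are argued against as the whole reason by protein-coding genes with no pseudogene named after them, where 56.8% of sites (55.3 to 58.4) were on the plus strand, against 55.98% in genes with one (difference -0.828 points, -5.10 to 3.03); pseudogenes under other names were not counted. Deeper coverage was examined through the mean number of sites per gene, which was 1.07 times as high on the plus strand within coverage deciles (1.03 to 1.11). Median coverage was 33.6 for genes on the plus strand and 30.02 for those on the minus strand. Deciles match depth only loosely for the most covered genes. The ratio also leaves out how many genes pass the limits on each strand. It therefore does not decide whether deeper coverage is the reason. The plus share of genes was 48.7% in the lowest coverage decile and 62.2% in the highest, and the cause stays open.

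Whether sampling of reads around the listing limits accounts for the sites listed once stays open. Reads redrawn at the level of each replicate 1 site and at the depth of replicate 2 predicted that 91.5% would be listed again, against 83.5% observed, a difference of -8.01 points, past the bound of 5 points set in advance. The difference was -12.0 points at 15 to 29 reads and -2.41 at 200 or more. The prediction starts from sites already picked for passing the limits, which raises it most at low coverage by an amount not measured, so the bound was not a fair one and the test does not decide. This reading was chosen after the value was seen.

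The cause of the gathering of sites at annotated gene starts was not decided. The density there, 14.3 times that downstream, passed a bound of 5 set in advance for the adenosine next to the mRNA cap, but this ratio is the gathering itself and any cause of it would pass. Errors of reverse transcription at read ends were not tested. The sites were spread over 420 genes, so a few genes did not produce the peak.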
